A study of Mus musculus with 2 samples.

How the data were processed

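MicroRNA sequencing was run on hindbrain dissected from mouse embryos at embryonic day 13.5, a stage at which hindbrain neurons are being born. The embryos were of strain B6NCrl, healthy, with males and females pooled. The 2 libraries of short RNA, named replicate 1 and replicate 2 after the biological replicate numbers of the labels, form 1 group. Both carry the same donor identifier and separate biosample identifiers. Beyond the words biological replicate nothing in the sources used here says whether they came from separate litters, so the spread between them may be partly technical.

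The deposited values are raw read counts per microRNA gene, 1 table per library. Reads had been aligned to mm10 and counted on the GENCODE M4 annotation, per the README text deposited with the tables. The aligner, the counter, their versions and any adapter trimming are not given in the sources used here. Each table held 3 count columns: reads on either strand, reads on the annotated strand and reads on the opposite strand. The either-strand column equalled the sum of the other columns in every gene row, with 0 rows that differed in either library. The README does not name the strand columns, so the strand column with the larger total, 98.1% of the gene counts in each library, was taken as the annotated strand and used for all values, except in the alternative with the either-strand column. The opposite-strand column was kept for the closing section. Each table had 1973 gene rows and 4 summary rows for unmapped, multimapping, unassigned and ambiguous reads. In replicate 1 the gene rows of the annotated-strand column held 49.0% of 6141045 reads, multimapping reads 33.9%, unmapped reads 14.0% and reads outside any feature on that strand 3.15%. In replicate 2 the gene rows held 47.5% of 9486700 reads, multimapping reads 34.5%, unmapped reads 14.6% and reads outside any feature 3.39%. No read was listed as ambiguous in either library. The summary rows stayed out of the library sizes and tests.

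Because multimapping reads were set aside by the authors' counting, a microRNA made from several near-identical hairpins can have fewer counts in these tables than it has reads. Hairpin sequences from the GENCODE M21 transcripts were compared for shared stretches of 20 nt. Of the 1894 hairpins with a sequence, 923 shared at least 1 such stretch with another, among them 80 of the detected genes. Values of these genes are uncertain and are marked where they are printed. No unique molecular identifiers are named in the sources used here, so intervals and floors cover counting error only.

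Gene names, coordinates and host genes were taken from GENCODE M21 on GRCm38, the assembly that mm10 also denotes. The gene identifiers matched 1894 names. The remaining 79 rows had at most 1 count in a library. A microRNA gene that overlapped a gene of another kind on the same strand, protein-coding genes first, was called exonic where it overlapped an exon of that host and otherwise intronic. Without such a host it was called intergenic.

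Levels are given as CPM, the counts of a gene per 1000000 counts in the gene rows of its library, which totalled 3006571 counts in replicate 1 and 4508244 in replicate 2. A gene was detected with at least 10 counts in both libraries, which is 3.33 CPM in replicate 1 and 2.22 CPM in replicate 2. A count of 0 allows up to 3 counts, which is 0.998 CPM in replicate 1 and 0.665 CPM in replicate 2. The spread between the libraries was the common biological coefficient of variation (BCV) from edgeR 4.0.16 with trimmed-mean (TMM) library sizes and an intercept-only design. With 1 group, edgeR's quasi-likelihood test between groups could not be run. Each detected gene was instead compared between the libraries by a two-sided exact binomial test on its counts given the TMM library sizes, with Benjamini-Hochberg adjustment over the detected genes at a threshold of 0.05. This test compares these libraries, not conditions, and takes counting error as the only error. The edgeR exact tests named below add a spread between replicates, but with 1 library on each side they give a ranking of genes and no evidence that a gene differs. A log2 ratio is replicate 2 over replicate 1 with TMM scaling and no pseudocount.

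Before the data were examined, 15 lists of microRNA genes were fixed. They covered neuronal genes, the let-7, mir-99/100 and mir-125 families, the mir-17 family clusters, the Hox clusters, the oligodendrocyte lineage, the pluripotency clusters, the imprinted Dlk1-Dio3 domain, choroid plexus and multiciliated cells, sensory cells, blood, endothelium and mural cells, muscle, mesenchyme, epithelia, and liver, gut and pancreas. For each list the CPM of its members were summed, with exact Poisson 95% intervals per library. The median of log2(CPM + 1) was placed among 10000 random lists of the same size. The named genes were fixed by a rule at the same time: the 20 genes with the highest mean CPM, the 3 highest members of each list, every member of lists of 6 or fewer, and the 5 genes with the largest absolute log2 ratio among those with a mean of at least 100 counts. These made 59 genes, and any gene named outside the rule is marked as chosen after its values were seen. The comparison of whole lists between the libraries was added after seeing the data. It places a list's median log2 ratio among 10000 random lists, each member drawn from the 40 detected genes nearest in level. Because neighbours along the genome are not independent, the median was also placed among the 355 medians given by moving the whole list stepwise through the detected genes in genome order.

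Alternatives were the either-strand column, detection at 1 or 50 counts, totals or DESeq2 1.42.0 size factors for scaling, CPM totals with the summary rows or without the most abundant gene, Fisher's exact test, and edgeR's exact test with a preset BCV of 0.1. Each library was also left out in turn. An edgeR exact test with the BCV estimated from these libraries was added after seeing the data. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3, were used.

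The steps were tested on data simulated from the real means and library sizes of the 1973 genes. A BCV of 0.1 was estimated as 0.101 ± 0.00508 and a BCV of 0.2 as 0.199 ± 0.00882 (SD over 20 runs each). In a simulated comparison of the libraries with counting noise alone and 369 genes tested, the exact binomial test recovered 37 of 54 genes changed 1.5-fold (68.5%) and 52 of 58 genes changed 2-fold (89.7%). It called 1 of 257 unchanged genes. With the measured BCV of 0.141 added and no gene changed, it called 49.0% ± 1.94 of the genes tested (SD over 20 runs), so where libraries vary by that much a call by this test does not separate a gene from the common spread.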

Results

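The microRNA content of the embryonic day 13.5 mouse hindbrain was measured in 2 biological replicates by sequencing of short RNA. Replicate 1 held 3006571 reads counted on the annotated strand of microRNA genes and replicate 2 held 4508244, a depth ratio of 1.5. With at least 10 counts in both libraries, 356 microRNA genes were detected, 18.0% of the 1973 gene rows and 99.97% of the counts. In 1256 rows both libraries had 0 counts. The design has 1 tissue at 1 stage, so the account gives levels within this tissue and the comparison of its libraries, and no comparison between conditions.

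Multimapping reads, 33.9% and 34.5% of reads in replicates 1 and 2, are in no gene row, so ranks hold among counted reads only. Among these, the hindbrain profile was led by Mir99a, a member of the mir-99/100 family, at 175134 ± 19217 CPM (SD, n = 2), or 17.5% ± 1.92 of the counts. Mir10a, which lies in the HoxB cluster and belongs to a family tied to hindbrain and trunk patterning, followed at 84053 ± 12284 CPM. Mir100, of the same family as Mir99a, stood at 53015 ± 2526 CPM. Mir335, carried in an intron of the imprinted gene Mest, reached 44867 ± 2238 CPM, and Mirlet7g, of the let-7 family that accumulates as cells differentiate, 41484 ± 5795 CPM (n = 2 for each). Mir10b, in an intron of Hoxd4, had 37089 ± 4311 CPM, and Mir17, first hairpin of a polycistron active in proliferating progenitors, 36088 ± 1368 CPM.

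The loci of these genes were chr16:77598936-77599000 for Mir99a (ENSMUSG00000065530.1, intron of the non-coding host Mir99ahg) and chr11:96317165-96317274 for Mir10a (ENSMUSG00000065519.1, intergenic), on GRCm38. Mir100 lay at chr9:41531425-41531504 (ENSMUSG00000093011.1, intron of the long non-coding RNA gene Gm49317). Mir335 lay at chr6:30741299-30741396 (ENSMUSG00000065501.1), Mirlet7g at chr9:106178840-106178927 (ENSMUSG00000065440.1, intron of Wdr82), Mir10b at chr2:74726070-74726137 (ENSMUSG00000065500.2) and Mir17 at chr14:115043671-115043754 (ENSMUSG00000065508.1, exon of Mir17hg).

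The 10 most abundant genes, which also included Mirlet7i, Mir130a and Mir99b, held 54.9% ± 0.110 of the counts (SD, n = 2). The 20 most abundant held 70.2% and the 50 most abundant 86.3%. Mirlet7i had 27985 ± 2333 CPM, Mir130a 26076 ± 267 CPM and Mir99b, in an intron of Spaca6, 23142 ± 2945 CPM. Mir487b of the imprinted Dlk1-Dio3 domain had 23111 ± 2664 CPM and shared 1 of its 63 stretches of 20 nt with Mir376b. The endothelial Mir126a, in an exon of Egfl7, had 19729 ± 1148 CPM. The rest of the 20 were Mir93, Mir30e, Mir26b, Mir181c, Mir20a, Mir149, Mir30a and Mir181d, from 17605 ± 922 CPM for Mir93 down to 8661 ± 162 CPM for Mir181d. Of the detected genes, 166 lay in introns of host genes with 56.9% of the counts, 89 lay in exons with 19.7%, and 101 were intergenic with 23.4%.

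**Figure D1:**
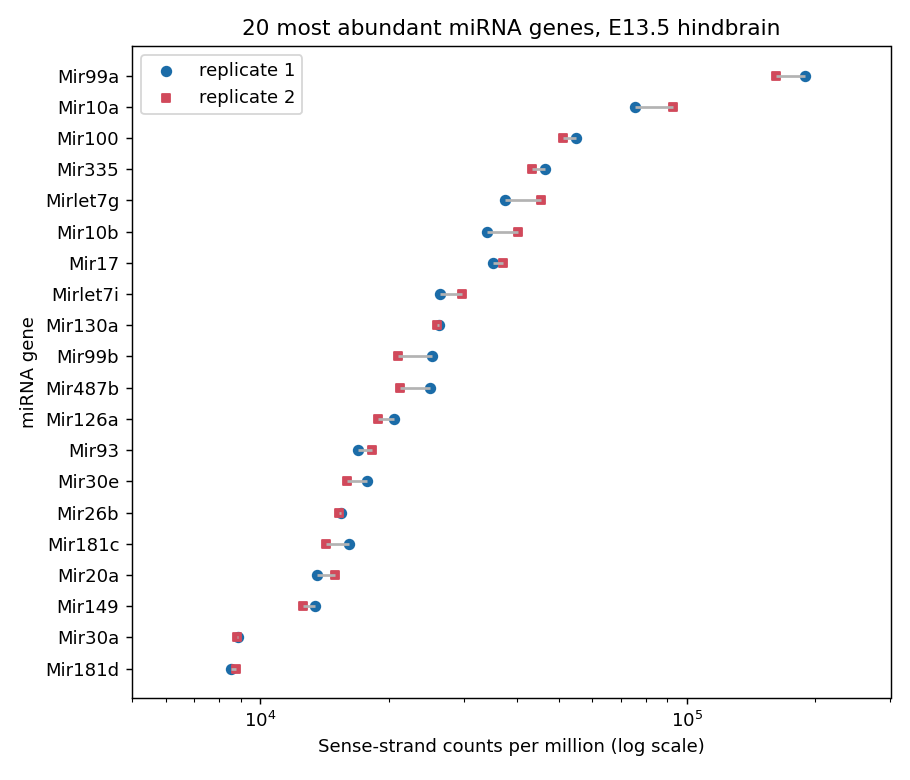
CPM on a log axis for the 20 most abundant microRNA genes, with replicate 1 as circles, replicate 2 as squares and a grey line joining them. Mir99a, at 188722 CPM in replicate 1 and 161545 CPM in replicate 2, lay above every other gene in both libraries.

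Among the fixed lists, the let-7, mir-99/100 and mir-125 list and the Hox cluster list took the largest summed shares. The 16 measured members of the let-7, mir-99/100 and mir-125 families were all detected and summed to 340950 ± 14379 CPM, or 34.1% ± 1.44 of the counts (SD, n = 2), most of it from Mir99a, Mir100 and Mirlet7g, while 7 of the 16 share stretches of 20 nt with another hairpin. Mirlet7e and Mirlet7f-1, chosen after their opposite-strand counts were seen, have no row of their own and are not in this sum. The Hox cluster list, with 4 of 6 members detected, summed to 123589 ± 17127 CPM. Behind Mir10a and Mir10b in it stood Mir615, in an intron of Hoxc5, at 2420 ± 519 CPM and Mir196b, annotated in an exon of Hoxa9, at 26 ± 11.8 CPM. Mir196a-2 had 2 and 7 counts in replicates 1 and 2, Mir196a-1 had 0 and 1, and these copies share 3 stretches of 20 nt, so their values are uncertain.

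The mir-17 family clusters, which are active in dividing progenitors, had 14 of 15 members detected and summed to 85536 ± 4165 CPM (SD, n = 2). Mir17, Mir93 and Mir20a, at 14286 ± 992 CPM for Mir20a, made up most of the sum. The Dlk1-Dio3 domain on chromosome 12, whose microRNAs are expressed from the maternal allele and are frequent in brain, had 41 of 45 members detected and summed to 73921 ± 4733 CPM. Its highest members were Mir487b, Mir369 at 7709 ± 586 CPM and Mir127 at 6490 ± 83.0 CPM. Mir409, Mir376a, Mir380 and Mir299a of this domain have no row of their own and are not in the domain's sum. They were chosen after their opposite-strand counts were seen. The pluripotency list had 7 of 12 members detected and a sum of 1851 ± 98.8 CPM, carried by Mir302a at 777 ± 75.7 CPM, Mir302d at 607 ± 23.8 CPM and Mir302b at 379 ± 6.92 CPM, of which Mir302a and Mir302b share a stretch of 20 nt.

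Among neural lists, the neuronal one had 16 of 20 members detected and summed to 13191 ± 115 CPM (SD, n = 2), or 1.32% of the counts. Mir137, a regulator of neuronal differentiation, had 6207 ± 105 CPM, Mir153, in an intron of Ptprn2, 1579 ± 180 CPM, and Mir138-1, which shares stretches with Mir138-2, 863 ± 23.3 CPM. Of the neuronal members 15 share a 20-nt stretch with another hairpin, and the 3 copies of Mir124a, the best known neuronal microRNA, were among the lowest, at 3.55 ± 2.20 CPM for Mir124a-1, 3.49 ± 1.65 CPM for Mir124a-2 and 1.22 ± 1.10 CPM for Mir124a-3, genes chosen after their values were seen. Reads set aside as multimapping were 33.9% and 34.5% of the reads in replicates 1 and 2. The oligodendrocyte list, with all 3 measured members detected, summed to 3253 ± 54.5 CPM, with Mir219a-2 at 2731 ± 103 CPM, Mir219a-1 at 279 ± 20.9 CPM and Mir338, in an intron of Aatk, at 243 ± 27.4 CPM. The Mir219a copies share 3 stretches. The sensory cluster of Mir182, Mir183 and Mir96, known from hair cells and photoreceptors, summed to 11320 ± 655 CPM, with Mir182 at 5535 ± 143 CPM, Mir183 at 4238 ± 459 CPM and Mir96 at 1547 ± 53.2 CPM.

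MicroRNAs of other cell types had sums that ran from 123 CPM for muscle to 26299 CPM for endothelium and mural cells. The choroid plexus and multiciliated list, 6 of 7 members detected, summed to 7342 ± 3325 CPM (SD, n = 2), with Mir449a, in an intron of Cdc20b and known from multiciliated cells, at 4451 ± 2223 CPM, Mir204, in an intron of Trpm3 and abundant in choroid plexus, at 1734 ± 682 CPM and Mir34c at 1106 ± 402 CPM. The endothelial and mural list had 3 of 4 members detected and summed to 26299 ± 1432 CPM, with Mir126a highest, Mir143 at 6490 ± 281 CPM and Mir145a at 80.6 ± 2.65 CPM. The liver, gut and pancreas list had 7 of 8 members detected and summed to 1818 ± 209 CPM, led by Mir375, known from endocrine cells, at 1087 ± 121 CPM, then Mir217 at 340 ± 67.6 CPM and Mir216b at 126 ± 24.9 CPM.

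The epithelial list had all 7 members detected and summed to 744 ± 79.7 CPM (SD, n = 2), with Mir203 at 513 ± 9.36 CPM, Mir429 at 84.5 ± 36.7 CPM and Mir200c at 56.9 ± 22.5 CPM. The mesenchyme list, 3 of 4 members detected, summed to 679 ± 200 CPM, with Mir214, carried in the Dnm3os transcript, at 491 ± 170 CPM and Mir199b, which shares stretches with both Mir199a copies, at 173 ± 29.8 CPM. The blood list had all 6 measured members detected and summed to 479 ± 25.8 CPM, with Mir155 at 164 ± 30.9 CPM, the myeloid Mir223 at 147 ± 7.80 CPM and the erythroid Mir451a at 105 ± 67.1 CPM. Mir142, chosen after its opposite-strand counts were seen, has no row of its own and is not in this sum. The muscle list had 3 of 9 members detected and summed to 123 ± 45.7 CPM, from Mir208b, in an intron of the cardiac and slow-muscle myosin gene Myh7, at 59.1 ± 58.5 CPM, the skeletal muscle Mir206 at 48.4 ± 22.3 CPM and Mir208a, in an intron of the cardiac myosin gene Myh6, at 9.48 ± 8.70 CPM.

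**Figure D2:**
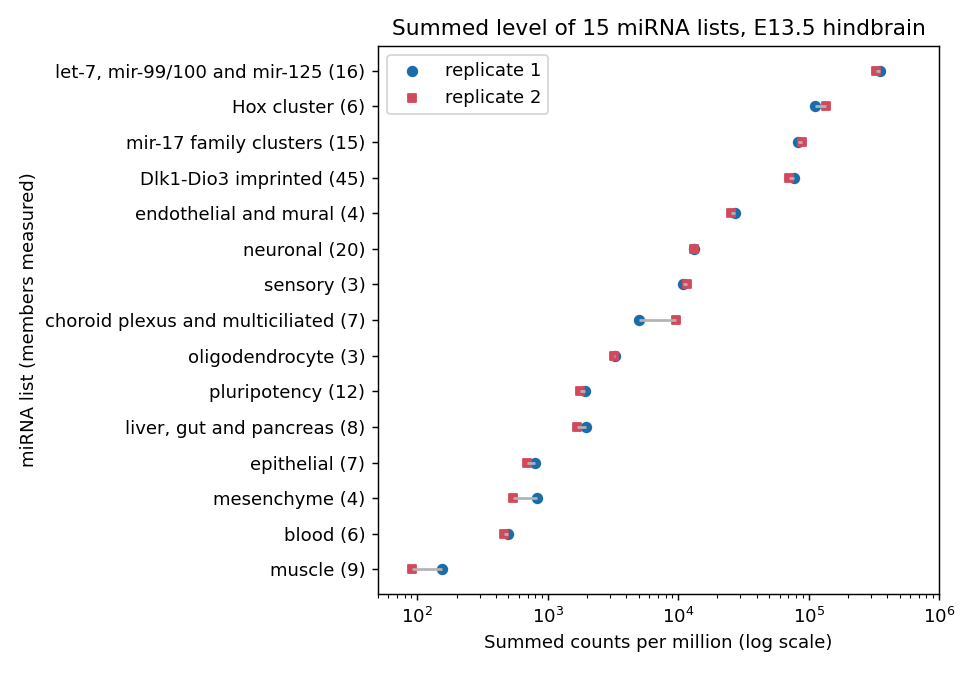
Summed CPM on a log axis for the 15 lists, with the number of measured members in brackets, replicate 1 as circles and replicate 2 as squares. The sums ran from 123 CPM for the muscle list to 340950 CPM for the let-7, mir-99/100 and mir-125 list, and the choroid plexus and multiciliated list had 4991 CPM in replicate 1 and 9694 CPM in replicate 2.

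Against random lists of the same size from all gene rows, every list's median lay at or above the 98.1 percentile, a background in which 1256 of 1973 rows had no counts. Against detected genes alone, only the detected members of each list were ranked. There the let-7, mir-99/100 and mir-125 list lay at the 99.99 percentile, the Hox cluster list at 99.8 and the Dlk1-Dio3 list at 99.5, while the pluripotency list lay at 13.2, the epithelial list at 15.9 and the blood list at 19.98. These percentiles describe genes of these libraries, and genes are not replicates.

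Among genes with a mean of at least 100 counts, the libraries differed most in Mir208b, Mir451a, Mir449a, Mir429 and Mir206. The cardiac and slow-muscle Mir208b was lower in replicate 2, at 17.7 CPM against 100 CPM in replicate 1 (log2 ratio -2.54), and its relative Mir208a was too, at 3.33 against 15.6 CPM (log2 ratio -2.27). The erythroid Mir451a had 57.5 CPM in replicate 2 and 152 CPM in replicate 1 (log2 ratio -1.44), and Mir429 of the epithelial mir-200 family 58.6 and 110 CPM (log2 ratio -0.95). Mir449a was higher in replicate 2, at 6023 against 2879 CPM (log2 ratio 1.03), as was Mir206, at 64.1 against 32.6 CPM (log2 ratio 0.94). Each of these values comes from 1 library.

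Across the 356 detected genes the common BCV was 0.141, the median absolute log2 ratio was 0.18 and the SD of the log2 ratio was 0.39. The libraries' log2 CPM correlated across genes, which are not independent replicates, with a Pearson r of 0.994 and a Spearman rho of 0.994. The counts differed by more than sampling noise, with a chi-square of 38605.6 on 355 degrees of freedom. By the two-sided exact binomial test with Benjamini-Hochberg adjustment 161 genes differed, 72 higher and 89 lower in replicate 2, against 92 higher and 77 lower with totals in place of TMM. Libraries simulated with a BCV of 0.141 and no changed gene gave 178 ± 6.99 such genes of 364 tested (SD, 20 runs). That BCV comes from the same libraries, so a similar number is built in, and the 161 calls are not evidence of differences beyond the common spread. Of the detected genes, 90.4% lay within 1.5-fold and 10 lay beyond 2-fold. With edgeR's exact test at a preset BCV of 0.1 the number was 13, of which 6 were higher and 7 lower. With the BCV estimated from the libraries, added after seeing the data, it was 5. Both tests set 1 library against 1 library, the preset BCV lies below the measured one, and the estimated BCV comes from the differences under test. They rank genes by distance from a common spread and cannot establish that any of them differs.

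The 5 furthest from that spread were Mir208b, Mir451a, Mir208a and Mir200b of the epithelial mir-200 family, all lower in replicate 2, and Mir449a, which was higher. Mir200b, at 23.8 CPM with a log2 ratio of -1.40, was chosen after its values were seen. None of the 20 most abundant genes was among the 13. The log2 ratio was -0.26 for Mir99a and 0.26 for Mir10a, both past the exact binomial test, which counts sampling error alone.

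The exact binomial test passed 45.2% of all detected genes, so the numbers past it in each list are no evidence of differences beyond the common spread. By list, all 6 detected choroid plexus and multiciliated genes were higher in replicate 2 in value, 4 of them past the exact binomial test (4 adjusted over the list alone), with a median log2 ratio of 0.67 (counting interval 0.57 to 0.90) at the 100 percentile of level-matched random lists. Mir449a and Mir449c are genomic neighbours, as are Mir34b and Mir34c, so the 6 are not independent. Mir449c had 5.88 CPM and Mir211 4.88 CPM. Mir449c, Mir34b and Mir211 were chosen after their values were seen. Mir449a, Mir204 and Mir34c were among the 13 genes, and only Mir449a among the 5. The 4 detected Hox cluster genes were higher too, all past the test (4 adjusted over the list alone), with a median of 0.34 at the 99.5 percentile and Mir196b highest at 0.93, but none was among the 13. Of the 7 detected epithelial genes 6 were lower in value, 4 past the test (4 adjusted over the list alone), with a median of -0.86 at the 0 percentile. Mir203, the most abundant, lay at -0.07 and Mir205 was higher at 0.26. The other members are of the mir-200 family. Mir429, Mir200a and Mir200b are genomic neighbours, as are Mir141 and Mir200c, so these genes are not independent. Mir205, Mir200a and Mir141 were chosen after their values were seen. Mir200b, Mir429 and Mir200c were among the 13, and only Mir200b among the 5. The Dlk1-Dio3 genes were lower in 33 of 41 cases, 23 past the test (24 adjusted over the list alone) with 3 past it in the other direction, and a median of -0.17, but none of the 41 was among the 13. These genes are neighbours in 1 domain, and the median lay at the 0 percentile of lists drawn gene by gene and at the 2.54 percentile of the list moved as a whole along the genome. The 3 detected muscle genes went both ways, 2 lower and 1 higher past the test (likewise adjusted over the list alone), with a median of -2.27 that became -0.66 without Mir208b. The mesenchyme genes had a median of -0.39 at the 1.73 percentile, with 2 of 3 past the test (2 adjusted over the list alone), Mir214 at -0.76, and a median of -0.17 without it. Mir214 was among the 13 and not among the 5. Moved along the genome as wholes, the mesenchyme list lay at the 2.82 percentile, the Hox cluster list at 99.7, the choroid plexus and multiciliated list at 100, and the epithelial and muscle lists at 0.

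The let-7, mir-99/100 and mir-125 list summed lower in replicate 2, at 330782 against 351117 CPM, while its median log2 ratio was 0.12, at the 99.6 percentile of lists drawn gene by gene and at the 95.8 percentile of the list moved along the genome. Of its 16 genes 8 were higher and 5 lower past the exact binomial test, with equal numbers adjusted over the list alone. Mirlet7g was higher at 0.25, Mir99b lower at -0.29 and Mir100 lower at -0.13. The other lists lay between the 7.06 and 89.3 percentiles of lists drawn gene by gene. Their median log2 ratios were 0.01 for the neuronal list (4 higher and 4 lower past the test), 0.06 for the mir-17 family clusters (8 and 1), 0.12 for the oligodendrocyte list (1 and 1), -0.11 for the pluripotency list (0 and 2), 0.04 for the sensory list (1 and 0), 0.04 for blood (1 and 1), -0.12 for endothelial and mural genes (0 and 2) and -0.19 for liver, gut and pancreas (0 and 3), with equal numbers adjusted over each list alone. Mir451a of the blood list was the only gene of these lists and of the let-7, mir-99/100 and mir-125 list among the 13. No list's median changed sign between TMM, totals and DESeq2 size factors, and the median of all detected genes lay at -0.01, 0.02 and -0.02 under these scalings.

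**Figure D3:**
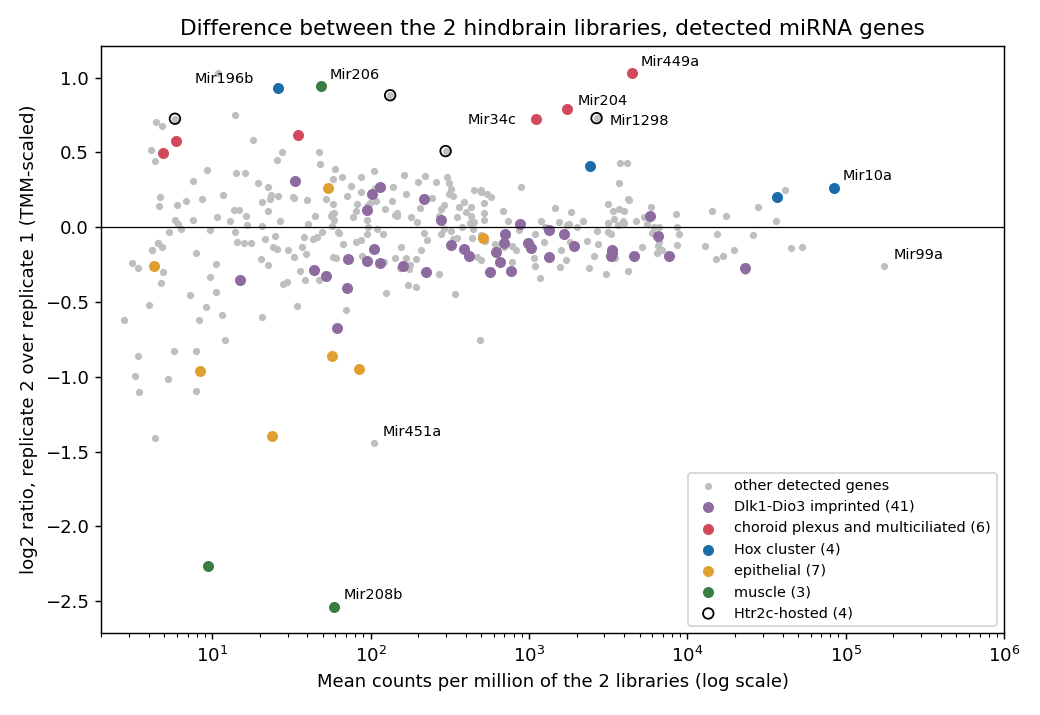
Log2 ratio of replicate 2 over replicate 1 against mean CPM on a log axis for the 356 detected genes, with members of 5 lists in colour and the 4 detected genes hosted in Htr2c, a set chosen after seeing the data, circled. The 6 choroid plexus and multiciliated genes all lie above 0, Mir208b lies lowest at -2.54, and Mir99a lies at -0.26.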

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

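Of the tests in this part, those of a low tissue level, of strand specificity, of choroid plexus tissue, of a lower neural share and of GC content were chosen only after the result was seen.

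The Mir124a copies and Mir9-2, neuronal microRNAs usually abundant in brain and chosen after their values were seen, had almost no counts: Mir9-2 stood at 3.16 ± 0.236 CPM (SD, n = 2) and the Mir124a copies at 3.55 CPM or less. All share stretches of 20 nt with their copies, 25 of 66 stretches in Mir124a-1 and 28 of 53 in Mir9-2, while Mir9-3, a further copy also chosen after its values were seen, shares 13 of 71 and had 573 ± 65.5 CPM. A test across list members could not decide a loss of their reads as multimapping, since it compares different genes and takes any number of shared stretches alike. The median log2(CPM + 1) of members with a shared stretch minus that of members without one was -1.78 (two-sided permutation p = 0.0693 across 49 and 116 genes). The 49 include these 4 genes, and without them the difference was -0.98 (permutation p = 0.415). Reads set aside as multimapping were 34.2% ± 0.425 of all reads, which leaves room for such a loss and does not test a low level in the tissue, since their genes are not given in the sources used here. A loss of reads and a low level in the tissue, the biological explanation, cannot be told apart, because no table assigns the multimapping reads to genes.

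Counts on the strand opposite to annotated genes, which enter the report's values nowhere and otherwise only the either-strand alternative, exceeded the 3 counts that a 0 allows at several genes, chosen by these counts and given here as sums over both libraries. The highest were 40383 at Gm24321 (chr12:109743158-109743237, opposite Mir409), 34177 at Gm25927 (opposite Mirlet7e), 25499 at Gm25252 (opposite Mir376a), 15703 at Gm24083 (opposite Mir191), 13938 at Gm25301 (opposite Mir378a) and 6237 at Gm25750 (opposite Mir380), where the annotated strand had 0 counts in both libraries. Next came 4086 at Mir299b (opposite Mir299a), 2232 at Mir497b (opposite Mir497), 1637 at Mir142b (opposite Mir142), 443 at Gm25641 (opposite Mir9-1) and 395 at Gm24111 (opposite Mirlet7f-1), where the annotated strand had between 0 and 9 counts per library. Smaller sums were 102 at Mir203, 91 at Mir3074-1 (opposite Mir24-1), 43 at Mir708, 13 at Mirlet7b, 11 at Mir183, 9 at Mir7654 and 9 at Mir337 (opposite Mir3544).

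Incomplete strand specificity is argued against, because the 20 most abundant genes had 0.000395% ± 2.59e-05 of their counts on the opposite strand (SD, n = 2), while all genes together had 1.88% and 1.904% in replicates 1 and 2. Reads of a microRNA annotated on the other strand of the same locus remain the candidate explanation, with 99.8% ± 0.0208 of the opposite-strand counts at the 32 genes, 1.62% of all, that have such a partner in GENCODE M21. None of these partners, among them Mir409, Mirlet7e, Mir376a, Mir191, Mir378a and Mir142, has a row of its own among those analysed here, so they enter no list sum. No biological explanation was tested.

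All 6 detected choroid plexus and multiciliated genes, some of them genomic neighbours and so not independent, were higher in replicate 2, with a median log2 ratio of 0.67. They were led by Mir449a at 2879 and 6023 CPM and Mir204 at 1252 and 2216 CPM in replicates 1 and 2. A lower share of neural tissue that raises every other cell type alike is argued against, for these libraries only, by the 29 detected genes of the blood, endothelial and mural, muscle, mesenchyme, epithelial, and liver, gut and pancreas lists. Their median log2 ratio was -0.19 (95% bootstrap interval over genes -0.44 to 0.0052). Hairpin GC content is argued against by the detected genes nearest to the list in GC content, whose median log2 ratio was -0.038 (bootstrap interval over genes -0.074 to 0.025). Both intervals cover the choice of genes, some of them genomic neighbours, and not the spread between replicates. More choroid plexus tissue in replicate 2 stays open: microRNAs in introns of Htr2c, a serotonin receptor gene abundant in choroid plexus and also expressed by neurons, are in none of the lists and had a median log2 ratio of 0.73 over 4 detected genes, with Mir1298 at 1983 and 3366 CPM, Mir448 at 242 and 353 CPM and Mir1264 at 92.1 and 174 CPM. These genes were chosen after their values were seen, so they do not decide it: they lie in 1 host gene on chromosome X, their median lay at the 99.9 percentile of the set moved along the genome, edgeR's exact test called Mir1298 and Mir1264 at a BCV of 0.1 and none at the estimated BCV, and how the tissue was divided at dissection is not given in the sources used here. The design has no group that would test a biological explanation.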

How the results depend on the processing

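The comparison of whole lists between the libraries, the test with the estimated BCV and the thinning of counts were chosen after seeing the data. With 10 counts required in both libraries 356 genes were detected, with 1 count 587, and with 10 counts after both libraries were thinned to 50% 324 (mean of 20 draws). The number of genes differing between the libraries stayed between 158 and 170 under the other scalings, filters, strand column and Fisher's exact test, and was 13 with edgeR's exact test at a BCV of 0.1 and 5 at the estimated BCV, since these tests add spread between replicates to sampling error. The share of the 10 most abundant genes was 53.9% with both strands counted, 26.5% with the summary rows in the total and 48.1% without Mir99a. The BCV stayed between 0.138 and 0.143. TMM and DESeq2 sizes kept all 15 list sums and all 59 gene values within 1 SD. That is uninformative, since both were rescaled to the average of the totals, which leaves a mean of 2 libraries almost unchanged by construction. No list's median log2 ratio changed sign between TMM, totals and DESeq2 size factors. The balance of genes differing did turn, from 72 higher and 89 lower in replicate 2 to 92 higher and 77 lower with totals and with Fisher's exact test, which also uses totals. No paired analysis was possible because the design has 1 group.

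With the summary rows in the total, which lowers every value by construction, the list sums were 6363 CPM (neuronal), 164548 (let-7, mir-99/100 and mir-125), 41242 (mir-17), 59533 (Hox), 1570 (oligodendrocyte), 893.6 (pluripotency), 35684 (Dlk1-Dio3), 3525 (choroid plexus and multiciliated), 5457 (sensory), 231 (blood), 12694 (endothelial and mural), 59.6 (muscle), 329 (mesenchyme), 359 (epithelial) and 878 (liver, gut and pancreas). Without Mir99a in the total, which raises the other lists by construction, they were 15995 CPM (neuronal), 201008 (let-7, mir-99/100 and mir-125), 103666 (mir-17), 149628 (Hox), 3946 (oligodendrocyte), 2246 (pluripotency), 89707 (Dlk1-Dio3), 13718 (sensory), 581 (blood), 31912 (endothelial and mural), 904 (epithelial) and 2207 (liver, gut and pancreas). With both strands counted, the neuronal sum was 12943 CPM and the oligodendrocyte sum 3193 CPM.

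With detected genes as the background, only the detected members of each list were ranked, so undetected rows left both the lists and the background. For the Hox list this moved the median from 1223 CPM over its 6 measured members to 19754.5 CPM over its 4 detected ones. Median percentiles were then 91.1 (neuronal), 95.2 (mir-17), 59.9 (oligodendrocyte), 13.2 (pluripotency), 54.8 (choroid plexus and multiciliated), 96.6 (sensory), 19.98 (blood), 98.5 (endothelial and mural), 23.2 (muscle), 51.5 (mesenchyme), 15.9 (epithelial) and 31.2 (liver, gut and pancreas). Leaving out each library in turn gave the muscle list percentiles from 96.6 to 98.6, and for list sums and gene values it is uninformative, since with 2 libraries each value lies within 1 SD of the mean by construction. The median log2 ratio with totals was 0.37 for the Hox list and -0.089 for the endothelial and mural list. Without its most abundant member it was 0.41 for the Hox list, 0.11 for the sensory list, -0.66 for the muscle list and -0.17 for the mesenchyme list, and the muscle list had -0.80 with 50 counts required. The cause was not tested for these shifts.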

Other observations

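Within 10000 bp on the same strand, 151 detected genes formed 44 clusters of at least 2, with 55.8% of the counts. The highest member exceeded the lowest more than 10-fold in 29 clusters and less than 2-fold in 7, with a median of 18.6-fold. Some lowest members, such as Mirlet7c-1, Mirlet7a-2 and Mir19b-1, share stretches with other hairpins. Their reads may have been set aside as multimapping, so these folds are uncertain. Mir374b and Mir421 were closest, at 1.03-fold. The Mir17 cluster on chromosome 14, carried in exons of Mir17hg, summed to 57046 ± 2678 CPM (SD, n = 2), yet its 6 hairpins ran from Mir17 at 36088 ± 1368 CPM through Mir18 at 4743 ± 183 CPM and Mir92-1 at 1854 ± 124 CPM to Mir19a at 66.0 ± 12.01 CPM and Mir19b-1 at 10.5 ± 2.04 CPM. Mir19a shares no stretch of 20 nt with another hairpin, whereas Mir19b-1 shares 6 of 68 and Mir92-1 3 of 61. Mir99a, at 175134 CPM, lay next to Mirlet7c-1, at 305 ± 55.3 CPM, in the same host Mir99ahg, and Mir100, at 53015 CPM, lay next to Mirlet7a-2, at 168 ± 20.98 CPM. Mirlet7c-1 and Mirlet7a-2 share stretches with other let-7 hairpins and are uncertain. Mir18, Mir19a, Mir19b-1, Mir92-1, Mirlet7c-1, Mirlet7a-2, Mir374b and Mir421 were chosen after their values were seen.

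Clusters were set by position, so their members and sums are not those of the fixed Dlk1-Dio3 list. The Dlk1-Dio3 domain formed a cluster of 30 detected hairpins at chr12:109709060-109747960 that summed to 56946 ± 3968 CPM (SD, n = 2), another of 10 at chr12:109563692-109594599 that summed to 15521 ± 644 CPM, and one of 3 at chr12:109611500-109618336 that summed to 1484 ± 126 CPM. In the first, members ran from Mir487b at 23111 CPM to Mir544 at 14.97 CPM. In the Mir302 cluster on chromosome 3, Mir302a, Mir302d and Mir302b had 777, 607 and 379 CPM. Of their neighbours with no shared stretch, Mir302c had 47.3 ± 7.36 CPM and Mir367 had 0 counts in both libraries, which allows up to 0.998 CPM in replicate 1 and 0.665 CPM in replicate 2. Mir544, Mir302c and Mir367 were chosen after their values were seen. No test was run on these differences.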
